A study of Homo sapiens with 8 samples.

How the data were processed

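Gene expression was measured by RNA sequencing in 8 libraries from a brain metastatic derivative of MDA-MB-231, an established human breast cancer cell line. The cells carried a non-targeting shRNA (the control), an shRNA against MYC (the knockdown), the MYC shRNA with an empty vector, or the MYC shRNA with MYC put back (the rescue), and each of these 4 groups had 2 libraries. Per the labels' protocols, cells grew for 2 days in DMEM with 10% fetal bovine serum, and strand-specific libraries were made from poly(A)-selected RNA and sequenced as single-end reads of 50 nt on a NextSeq 500. Per the series' design text, reads were aligned to the human genome with STAR 2.5. The submitters' processing notes name the build GRCh38 and also list R 3.2.5 and GenomeStudio 2010.1, without saying what each was used for. The gene annotation and the counting tool are not given in the sources used here.

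The deposited table holds log2 values for 29748 rows, of which 4 collect reads not assigned to a gene (unmapped, multi-mapping, outside any feature, and ambiguous). In each column, 2 to the power of the deposited log2 value, minus 1, summed to 1e6 with those 4 rows included, so the authors' values are log2(CPM + 1), where CPM is reads per 1e6 reads of all kinds. All values (100%) were whole multiples of the worth of 1 read, within 0.1 read, which gave the depth of each library. Libraries held 24.8 to 30.6 M reads (M, 1e6), of which 17.6 to 22.6 M (70.4 to 73.8%) were assigned to genes. Multi-mapping reads made up 12.4 to 15.9% of a library, reads outside features 9.61 to 12.6%, ambiguous reads 1.62 to 1.79% and unmapped reads 0.727 to 1.20%. A single read was worth 0.0327 to 0.0403 CPM, and the limit that a count of 0 allows (3 reads) was 0.0980 to 0.121 CPM per library; such limits and all counting intervals cover counting error only. Gene names of 28 rows had been turned into dates in the file; 19 of them passed the filter and stayed in the tests without being named. Another 7186 rows were at 0 in every library.

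The design fixed before the data were examined named a count model for raw counts and limma for normalized values; as the file holds log2 normalized values, the count model was not used. Genes at 1 CPM or more in at least 2 of the 8 libraries were kept (12625 genes). A linear model with a term per group was fitted to the deposited log2 values of all 8 libraries with limma 3.58.1 in R 4.3.3, with a mean-variance trend, which left 4 residual degrees of freedom per gene. The comparisons were knockdown minus control, rescue minus vector, vector minus knockdown, rescue minus control, and the sum of the first pair of changes, which is 0 for a gene whose knockdown change the rescue takes back in full. Tests of genes and lists were two-sided, and their p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Fold changes are on the log2(CPM + 1) scale, which understates the change of genes with low levels. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

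Before the data were examined, 33 gene lists were fixed, and the 30 with at least 5 members past the filter were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 30 lists. An estimated correlation, and limma's fry, which asks whether the genes of a list move on balance one way without setting them against other genes, were alternatives. The lists covered the MYC and MAX network, growth and biosynthesis, the cell cycle, metabolism, apoptosis, stress, interferon and inflammation, adhesion, invasion and metastasis, and markers of luminal epithelial, fibroblast, immune and neural cells. The genes named were also chosen by a rule fixed beforehand. They were MYC, GPX1 and the TRAIL genes in any case; for knockdown and rescue, the 10 genes per direction with the largest change among those past the threshold, with a mean of at least 10 CPM in the higher group and no overlap between the groups; 5 per direction by the same rule for the other comparisons; the 10 largest reciprocal genes per direction; and the 4 members of each list with the smallest p. Some genes that the rule chose are not reported here. Genes named outside it are said to have been chosen after their values were seen. Positions are whole gene spans from the RefSeq annotation of GRCh38.p14, in which 214 of the 217 genes named by the rule were found.

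The test was checked on simulated data with 200 changed genes spread over 3 fold sizes among the 12625 tested. For knockdown it recovered 83.6% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 100% of those changed 4-fold, and for rescue 85.1, 94.0 and 100%. Unchanged genes made up 7 of 191 calls for knockdown and 15 of 201 for rescue. The simulation gave every gene and group the same spread beyond counting, unlike these libraries. Its shares therefore do not give the recovery in these data. Alternatives fixed beforehand were quantile normalization, no filter, a stricter filter (a mean of at least 5 CPM over the 8 libraries), pseudocounts of 0.1 and 5, limma without a trend, a fit of the compared groups alone, the replicate number as a block, a fold change of at least 2, and leaving out each library in turn. After seeing the data, CPM per 1e6 gene reads, median-of-ratios scaling, and limma's voom on the recovered reads were added; voom called 3042 genes for knockdown and 39 for rescue. Libraries of a group differed by more than sampling noise (chi-square per gene of 7.11 to 47.3), as repeat preparations of the same RNA would too. Each library was treated as a replicate. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.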

Results

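RNA was sequenced from brain metastatic MDA-MB-231 cells in which MYC, a transcription factor that drives cell growth, was depleted by shRNA and then put back. The 4 groups were a non-targeting shRNA control, the MYC knockdown, the knockdown with an empty vector, and the knockdown with MYC restored, with 2 libraries in each and 24.8 to 30.6 M reads (M, 1e6) per library. Levels are given as mean CPM ± SD of the 2 libraries of a group. On the first principal component, which held 61.6% of the variance, the control libraries lay at -38.4 and -36.2 and the other 6 libraries between 3.79 and 18.8. Within the knockdown group, replicate 1 lay at 3.79 and replicate 2 at 18.8, beside 16.1 and 17.3 for the vector libraries and 9.27 and 9.46 for the rescue libraries. The second component held 17.7% of the variance. On it the knockdown libraries lay at -18.9 and -10.5 and the rescue libraries at 13.1 and 21.5. Between them were the vector libraries (-2.78 and -1.81) and the control libraries (1.19 and -1.81). The correlation between the libraries of a group, across genes, was 0.989 for the knockdown and 0.994 to 0.997 for the other groups.

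MYC itself (chromosome 8, 127735434 to 127742951, GRCh38) was checked first in every library. It stood at 99.2 and 95.2 CPM in the control libraries and at 61.9 and 46.2 CPM in the knockdown libraries, so that the mean fell from 97.2 ± 2.81 to 54.0 ± 11.1 CPM. The log2 change was -0.85 (95% interval -1.16 to -0.54, limma adjusted p = 0.00170). The vector libraries were at 62.4 and 55.2 CPM (58.8 ± 5.12) and the rescue libraries at 111 and 89.3 CPM (100 ± 15.6). Rescue minus vector was 0.75 (0.44 to 1.07), which missed the adjusted threshold (adjusted p = 0.0606) with the spread taken from all 8 libraries. It passed in a limma fit of the rescue and vector libraries alone (adjusted p = 0.00193). Leaving out each library in turn gave differences of 0.60 to 0.91. Rescue minus control was 0.04 (-0.27 to 0.35, adjusted p = 0.889), so the restored level could not be told from the control level at this spread. Reads were counted per gene, so endogenous MYC and MYC from a construct were not separated.

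**Figure D1:**
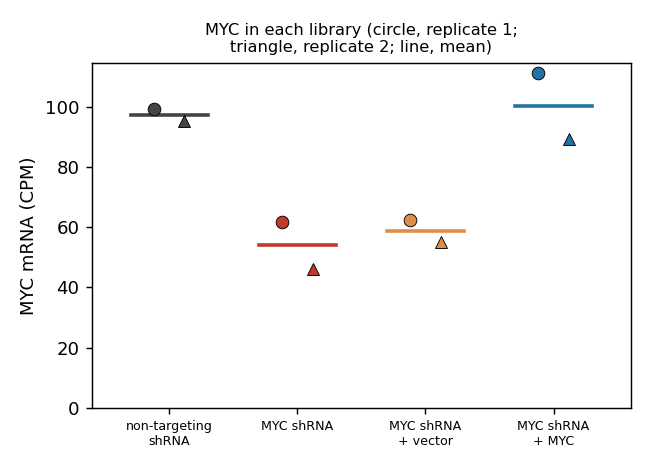
MYC mRNA in CPM (linear axis from 0) in each library of the 4 groups, with a circle for replicate 1, a triangle for replicate 2 and a line for the group mean. The knockdown and vector libraries sit between 46.2 and 62.4 CPM, and the control and rescue libraries between 89.3 and 111 CPM.

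The first comparison asked which transcripts differed once MYC was depleted. The 10 genes with the largest increases were at 3.71 CPM or less in the control. GLUL, glutamine synthetase (chromosome 1, 182378098 to 182391790), stood at 0.0528 ± 0.0177 CPM in the control and 41.2 ± 12.1 CPM after knockdown, a log2 change of 5.30 (SE 0.16, adjusted p = 2.6e-08); the control libraries held 3 GLUL reads together, and the pooled ratio was 753 with a counting interval of 257 to 3655. L1CAM, a neural cell adhesion molecule (chromosome X, 153861514 to 153886173), rose from 0.0692 ± 0.0408 to 18.5 ± 1.59 CPM (log2 change 4.19, SE 0.13). ITGB4, the beta 4 integrin that binds laminin (chromosome 17, 75721459 to 75757818), rose from 3.71 ± 0.290 to 61.5 ± 7.58 CPM (3.72, SE 0.11). The others with the largest increases were EPB41L3, a membrane skeleton protein (4.34), the cell adhesion molecule CADM1 (4.34), the proton-sensing receptor GPR65 (4.32), the aldehyde dehydrogenase ALDH3A1 (4.25), the monocyte chemokine CCL2 (3.93), KALRN (3.90) and RCN3, a calcium-binding protein of the endoplasmic reticulum (3.82). ALDH3A1 had 2 control reads, and its pooled ratio was 522 (144 to 4317).

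The largest decreases after knockdown were smaller and less even between the replicates. MYH10, a non-muscle myosin heavy chain, fell from 26.0 ± 1.34 to 5.82 ± 3.74 CPM (log2 change -2.10, SE 0.29, adjusted p = 6.1e-04). FAM84B, which lies on chromosome 8 at 126552443 to 126558478, fell from 15.3 ± 0.527 to 4.28 ± 0.320 CPM (-1.63, SE 0.13), and GALNT14, a glycosyltransferase, from 14.1 ± 0.774 to 3.42 ± 1.13 CPM (-1.80, SE 0.18). The ephrin receptor EPHA3 changed by -2.60, MAGEA3 by -2.59, the actin-bundling protein LCP1 by -2.30, PRRG4 by -2.20, G0S2, an inhibitor of fat breakdown, by -2.10, and the matrix protein TNC by -1.80. MAGEA3 shares near-identical sequence with other MAGE genes, so its 50-nt reads are uncertain. TNC averaged 31.2 ± 28.6 CPM after knockdown, with 51.4 CPM in replicate 1. Its call was lost without control replicate 1 (adjusted p = 0.12) or control replicate 2 (0.086), and without vector replicate 1 (0.0504) or vector replicate 2 (0.0506); that of G0S2 was lost without control replicate 1 (0.065).

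In all, 3079 of 12625 genes passed the threshold after knockdown, 1808 higher and 1271 lower, and 332 of the higher and 124 of the lower ones changed at least 2-fold. With 2 libraries per group the count depended on the controls. It was 1339 without control replicate 1 and 1708 without control replicate 2, and without knockdown replicate 1 it was 3981, with 47.8% higher in place of 58.7%.

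Among the fixed lists, genes that make ribosomes fell together. Of 40 ribosome biogenesis genes, 18 fell and none rose (23 lower adjusted over the list alone), with a median log2 change of -0.31 (camera adjusted p = 9.7e-09; adjusted p = 0.777 with an estimated correlation). LYAR changed by -0.91, NOP14 by -0.73, NOLC1, a nucleolar phosphoprotein, by -0.60 and HEATR1, a factor of ribosomal RNA synthesis, by -0.59. Of 75 proteins of the mitochondrial ribosome, 17 fell (15 adjusted over the list alone), among them MRPS21 (-0.92) and MRPL1 (-0.82) (camera adjusted p = 2.4e-05; adjusted p = 0.777 with an estimated correlation). Of 37 replication histones, which are made in S phase, 19 fell (27 lower and 1 higher adjusted over the list alone), such as HIST1H3A (-0.73) and HIST1H2BD (-0.47) (camera adjusted p = 2.5e-08; adjusted p = 0.528 with an estimated correlation). Histone genes are nearly identical to each other and mostly lack poly(A) tails, so single members are uncertain.

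Lists of adhesion, protease, interferon and luminal genes rose. Of 18 genes of epithelial-mesenchymal transition and adhesion, 10 rose (11 adjusted over the list alone), with a median of 0.34 (camera adjusted p = 1.7e-06; adjusted p = 0.528 with an estimated correlation). FN1, fibronectin, went from 36.3 ± 3.36 to 281 ± 64.3 CPM (2.90), and the epithelial keratins KRT19 and KRT8 rose by 1.34 and 1.18 beside ITGB4. Of 8 luminal epithelial markers, 5 rose (6 adjusted over the list alone), including KRT19 and KRT8, which the adhesion list also holds, AGR2 (2.03) and KRT7 (1.18) (camera adjusted p = 7.1e-04; adjusted p = 0.626 with an estimated correlation). Of 18 invasion proteases and their inhibitors, 7 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.00331; adjusted p = 0.777 with an estimated correlation). The collagenase MMP1 went from 119 ± 19.1 to 1424 ± 175 CPM (3.57), the plasminogen activators PLAT and PLAU rose by 2.19 and 0.89, and the protease inhibitor TIMP2 by 0.81. Of 26 interferon response genes, 8 rose and 2 fell (11 and 3 adjusted over the list alone; camera adjusted p = 0.00623; adjusted p = 0.777 with an estimated correlation), led by OASL (1.87), IFIT1 (1.85), IFIT2 (1.81) and IFIT3 (1.21). Without knockdown replicate 1, the protease and interferon lists no longer passed (adjusted p = 0.18 and 0.15). Of the 30 lists tested, 7 passed, 12 without knockdown replicate 1 and 11 without knockdown replicate 2.

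**Figure D2:**
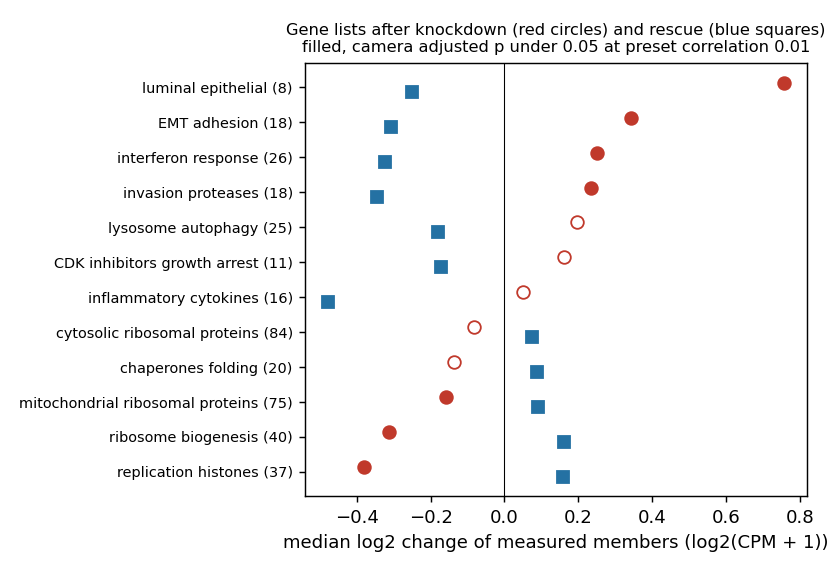
Median log2 change on the log2(CPM + 1) scale of the measured members (their number in brackets) of each gene list past the camera threshold in either comparison, after knockdown (red circles) and after rescue (blue squares). Filled symbols passed at an adjusted p under 0.05 with the preset correlation; ribosome biogenesis genes sit at -0.31 and 0.16, and adhesion genes at 0.34 and -0.31.

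The other lists did not pass the knockdown test. Growth lists held single members that changed. In nucleotide synthesis, 6 of 22 fell and 1 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.0675), with TYMS, thymidylate synthase, at -1.13, the purine enzymes PPAT and PAICS at -0.67 and -0.55, and the CTP synthase CTPS2 at 0.90; this list passed, lower, without knockdown replicate 2 (0.0042). In polyamine metabolism, 2 of 10 fell (3 adjusted over the list alone; 0.553), ODC1 by 0.72 and AMD1 by 0.51 on the log2 scale. In serine, one-carbon and glutamine metabolism, 3 of 18 rose (3 adjusted over the list alone; 0.278), GLUL and MTHFD2 (0.66) among them, and the list passed, higher, without knockdown replicate 1 (0.040). Cytosolic ribosomal proteins had 9 lower and 3 higher of 84 (7 and 3 adjusted over the list alone; 0.0604), a list that passed without control replicate 1 (0.021), without knockdown replicate 1 (0.040), and without rescue replicate 1 or rescue replicate 2 (0.040 each); their reads are shared with many processed pseudogenes. Chaperones had 3 lower and 2 higher of 20 (4 and 2 adjusted over the list alone; 0.0604), such as FKBP4 (-0.43) and CCT7 (0.43), and passed without control replicate 2 (0.036) or either rescue library (0.044 each). None of 20 tRNA synthetases passed (none adjusted over the list alone; 0.717), and of 10 MYC and MAX network genes MYC alone did (MYC alone adjusted over the list alone; 0.553).

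Cell cycle lists moved little. DNA replication genes had 2 lower of 32 (none adjusted over the list alone; camera adjusted p = 0.267), mitosis genes 2 lower and 1 higher of 25 (2 lower adjusted over the list alone; 0.586), with CCNA2, cyclin A2, at -0.52, and G1 cyclins and kinases 2 lower and 1 higher of 10 (3 and 1 adjusted over the list alone; 0.201), with CCND2, cyclin D2, at -0.85. CDK inhibitors and growth arrest genes (the CDK inhibitor list) had 3 higher of 11 (3 adjusted over the list alone; 0.273). These were CDKN2D, a CDK inhibitor, and the growth arrest genes NDRG1 and KLF6. The mitosis list passed, higher, without knockdown replicate 1 (0.040). Glycolysis had 1 higher of 21 (none adjusted over the list alone; 0.950), cholesterol synthesis 2 higher of 22 (1 adjusted over the list alone; 0.586), hypoxia 5 higher and 1 lower of 13 (the same counts adjusted over the list alone; 0.218), with ADM, adrenomedullin, at 1.51, and lysosome and autophagy 6 higher of 25 (7 adjusted over the list alone; 0.0782). The cholesterol list passed, higher, without knockdown replicate 1 (0.045), and the lysosome list without knockdown replicate 2 (0.001). ATF4 stress response genes had 1 lower of 18 (none adjusted over the list alone; 0.178), and immediate early genes 1 higher, DUSP1 (1.23), and 1 lower of 16 (1 higher adjusted over the list alone; 0.178). The ATF4 list passed, lower, without knockdown replicate 1 (0.045), and the immediate early list, also lower, without it (0.0059) or without control replicate 2 (0.020).

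Survival and metastasis lists were mixed. Of 12 BCL2 family genes, 3 rose and 1 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.870), with the survival proteins BCL2A1 at 2.21 and BCL2L1 at 0.48. Of 26 antioxidant genes, 3 rose and 1 fell (the same counts adjusted over the list alone; 0.935). Genes linked to spread of breast cancer cells to the brain or lung are called the brain metastasis list, or brain metastasis genes, here. Of the 21 measured in this list, 4 rose and 3 fell (4 and 4 adjusted over the list alone; 0.863), L1CAM and MMP1 among the higher ones, and PLOD2, a collagen lysyl hydroxylase, at 0.80. Its median was -0.38 without knockdown replicate 1 (adjusted p = 0.045) and 0.26 without knockdown replicate 2 (0.025). Of 16 inflammatory cytokine genes, 3 rose (3 adjusted over the list alone; 0.273), CCL2, IL11 (1.01) and IL1B (2.38). IL1B stood at 26.5 CPM in knockdown replicate 1 and 2.26 CPM in replicate 2, and its call was lost without control replicate 1 (0.12), control replicate 2 (0.15), vector replicate 1 (0.069) or vector replicate 2 (0.069). The list passed without knockdown replicate 2 (5.4e-09). Neural markers had 3 higher and 1 lower of 5 (the same counts adjusted over the list alone; 0.178), with MBP at 0.71, SYT1 at 0.76 and the glutamate transporter SLC1A3 at -1.55. Of the fibroblast and the immune markers 1 each was measured, COL1A1 (-0.04) and CD68 (0.49), too few for a test, and no mitochondrially encoded gene was in the table. The call of CD68 was lost without control replicate 1 (0.065) or control replicate 2 (0.082).

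GPX1, a glutathione peroxidase, and the TRAIL death receptors were to be named in any case by the rule fixed beforehand. GPX1 (chromosome 3, 49357176 to 49358353) was at 119 ± 21.7 CPM in the control and 127 ± 39.9 CPM after knockdown, a difference of 0.07 (95% interval -0.34 to 0.48, adjusted p = 0.810), and rescue minus vector was -0.01. Without knockdown replicate 2, the GPX1 difference after knockdown was 0.39 and passed (adjusted p = 0.049). TNFRSF10A (chromosome 8, 23190452 to 23225102) differed by -0.05 after knockdown (adjusted p = 0.800) and 0.16 after rescue (0.624). TNFRSF10B (chromosome 8, 23020133 to 23069031) differed by -0.08 (0.548) and -0.00 (0.997). TNFSF10, which encodes TRAIL, was at most 0.114 CPM in any library and below the filter. In the TRAIL pathway list 1 of 18 genes rose (1 adjusted over the list alone; camera adjusted p = 0.870), DIABLO (0.35), whose call was lost without control replicate 1 (0.077), control replicate 2 (0.051) or knockdown replicate 2 (0.053).

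**Figure D3:**
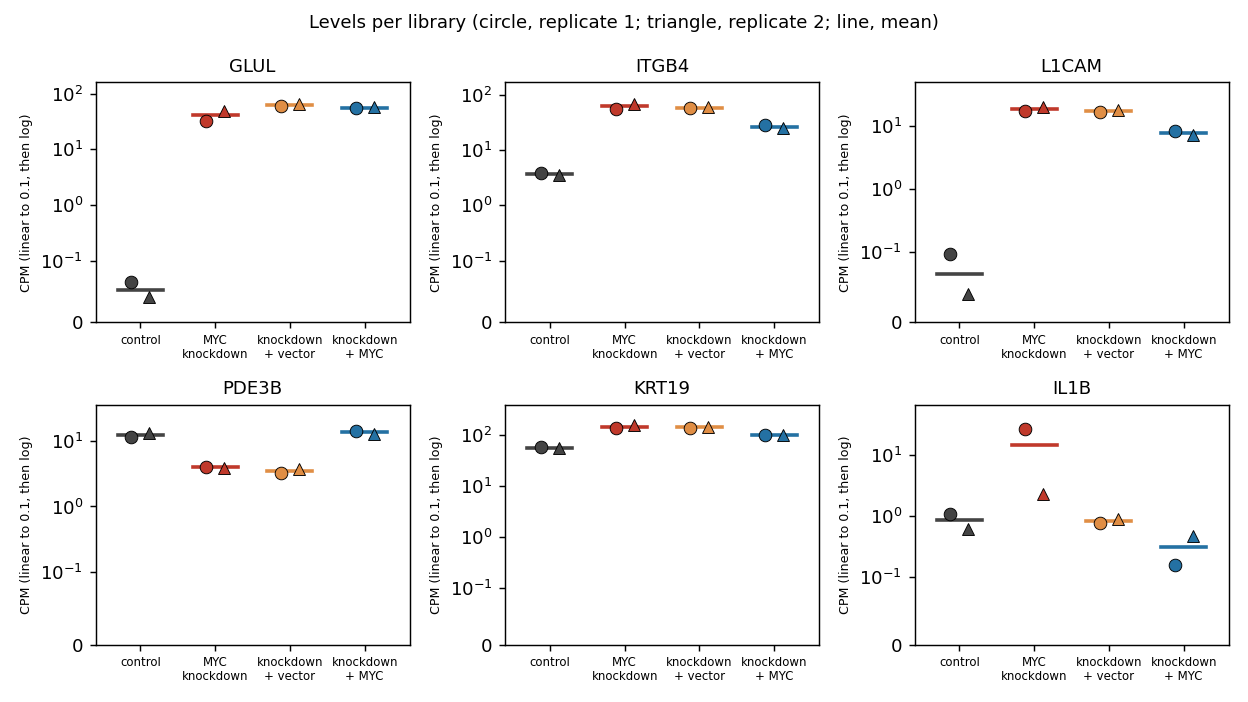
CPM of 6 genes in each library of the 4 groups (axis linear to 0.1 CPM, then logarithmic), with a circle for replicate 1, a triangle for replicate 2 and a line for the mean. GLUL stays high in the rescue libraries (56.3 CPM), ITGB4 and L1CAM fall part of the way, PDE3B returns to 13.6 CPM, and IL1B is 26.5 CPM in knockdown replicate 1 and 2.26 CPM in replicate 2.

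The next comparison asked what changed when MYC was put back, with the vector libraries as its control. PDE3B, a cyclic nucleotide phosphodiesterase (chromosome 11, 14643804 to 14899321), rose from 3.52 ± 0.385 to 13.6 ± 1.10 CPM (log2 change 1.69, SE 0.13, adjusted p = 8.8e-04), beside 12.3 ± 1.04 CPM in the control. The protocadherin PCDH7 rose by 1.32 and LRRC8B, a subunit of volume-regulated anion channels, by 0.96. The adhesion genes ITGB4 and L1CAM fell by 1.13 and 1.07 on the log2 scale, ITGB4 from 58.4 ± 2.82 to 26.2 ± 2.36 CPM (adjusted p = 0.00735) and L1CAM from 17.2 ± 0.601 to 7.72 ± 0.642 CPM (0.0118). SERINC2 changed by -1.27, PITPNM3 by -1.16, the antiviral enzyme OAS3 by -1.06, the matrix protein EFEMP1 by -0.96, PTGES, a prostaglandin E synthase, by -0.96, INHBB, an activin and inhibin subunit, by -0.89, CHST15, a chondroitin sulfotransferase, by -0.84 and SPECC1 by -0.81.

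In all, 38 genes passed, 4 higher and 34 lower; 1724 had an unadjusted p under 0.05. Under quantile normalization 6 of 27 calls were higher. The count rested on few libraries. It was 0 without vector replicate 1, 1 without vector replicate 2, 2 without rescue replicate 2, 61 without rescue replicate 1, 6 without control replicate 1, 6 without control replicate 2, 566 without knockdown replicate 1 and 568 without knockdown replicate 2. The control and knockdown libraries enter this comparison only through the shared spread, and all 38 genes were kept without either knockdown library and in a fit of the rescue and vector libraries alone, which called 452. Of the genes named here, PDE3B alone was still called without vector replicate 2, and none without vector replicate 1, where PDE3B had an adjusted p of 0.083, ITGB4 of 0.31 and L1CAM of 0.37; PDE3B and LRRC8B were the ones left without rescue replicate 2 (0.094 for ITGB4, 0.12 for L1CAM). PITPNM3, SERINC2, EFEMP1, PTGES, INHBB, CHST15, SPECC1 and PCDH7 also lost their calls without either control library (adjusted p 0.063 to 0.11).

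As lists, ribosome, chaperone and histone genes stood higher after rescue and adhesion, protease and interferon genes lower, at the preset correlation alone. All 40 ribosome biogenesis genes had a positive difference, with a median of 0.16 (camera adjusted p = 4.2e-11; adjusted p = 0.463 with an estimated correlation), though none passed over all genes (none adjusted over the list alone), with PPAN at 0.72, PNO1 at 0.29, DKC1 at 0.22 and NOLC1 at 0.20. Cytosolic ribosomal proteins (median 0.08, adjusted p = 1.7e-07), mitochondrial ribosomal proteins (0.09, 1.7e-07), chaperones (0.09, 1.2e-04) and replication histones (0.16, 6.5e-08) were also higher as lists, all with an adjusted p of 0.463 or more under an estimated correlation, with no gene called over all genes and, adjusted over the list alone, 4 histones. Adhesion genes were lower (median -0.31, camera adjusted p = 1.1e-06; adjusted p = 0.463 with an estimated correlation; 2 genes called, ITGB4 and TGFB2, and 10 adjusted over the list alone). Interferon genes were lower (-0.32, 1.7e-07; adjusted p = 0.463 with an estimated correlation; OAS3, IRF9 and OAS1 called, 11 adjusted over the list alone), as were, all with an adjusted p of 0.463 or more under an estimated correlation, proteases (-0.35, 2.3e-05; none called, 7 adjusted over the list alone), lysosome genes (-0.18, 2.9e-04; none either way), luminal markers (-0.25, 0.0209; none called, 3 adjusted over the list alone), cytokines (-0.48, 0.00378; none called, 2 adjusted over the list alone) and the CDK inhibitor list with its growth arrest genes (-0.17, 0.0131; none called, 3 adjusted over the list alone).

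These 12 of 30 lists passed at the preset correlation, and none passed with an estimated correlation, where the smallest adjusted p was 0.463, or with fry. Without vector replicate 1 the luminal list missed the threshold (adjusted p = 0.073), and without rescue replicate 1 the luminal (0.062), cytokine (0.051) and CDK inhibitor (0.22) lists did. Among the other lists, brain metastasis genes had a median of -0.13 (adjusted p = 0.0732; L1CAM called, 2 adjusted over the list alone) and passed without knockdown replicate 1 (0.0061), knockdown replicate 2 (0.0057) or vector replicate 2 (0.024). Hypoxia genes had a median of -0.21 (0.0740; none called, 4 adjusted over the list alone) and passed without knockdown replicate 1 (0.041), knockdown replicate 2 (0.041) or rescue replicate 2 (0.019).

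A gene that follows MYC should move one way after knockdown and back after rescue. These comparisons share no library, but in the model of all 8 libraries they share the estimate of each gene's spread. Their calls are therefore not independent, which the expected overlaps and p-values below do not allow for. Of the genes called in both, 28 were higher after knockdown and lower after rescue, where independent lists would share 4.87 (exact hypergeometric test, upper tail, unadjusted p = 1.1e-18, across genes that are not independent). They included ITGB4, L1CAM, SERINC2, PTGES, INHBB, PITPNM3, CHST15, the matrix protein ECM1, the interferon signalling factor IRF9 and DPYSL2, a cytoskeletal regulator of axon growth. PDE3B, LRRC8B and PCDH7 were lower after knockdown and higher after rescue (0.403 expected, p = 0.00377 by the same exact hypergeometric test), though the knockdown call of PCDH7 was lost without control replicate 1 (adjusted p = 0.091), control replicate 2 (0.098) or knockdown replicate 2 (0.065). PCDH7 was at 3.31 CPM in the control, 1.43 after knockdown, 5.49 with the vector and 15.1 after rescue, so the vector libraries did not share its decrease. OAS3 and SPECC1 were lower in both, and GALNT18, chosen here after its values were seen, was higher in both. In quantile-normalized values the opposite calls were 17 and 5 in place of 28 and 3. The 31 opposite calls became 0 without vector replicate 1, 1 without vector replicate 2, 2 without rescue replicate 2, 5 without control replicate 1, 5 without control replicate 2, 357 without knockdown replicate 1 and 343 without knockdown replicate 2. Across all 12625 genes the 2 sets of log2 changes had a Pearson correlation of -0.454 and a Spearman correlation of -0.462, a description across genes, which are not independent replicates.

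Most of the large knockdown differences were still there after rescue. Over the 456 genes changed at least 2-fold by knockdown, the rescue took back a median of 18.6% of the change, and over the 86 changed at least 4-fold 10.9%. By the sum of the 2 changes, 604 genes differed from a full reversal, 376 above and 228 below, and 318 of the 456 genes were among them. GLUL had the largest positive sum (5.15), at 62.3 ± 3.09 CPM in the vector libraries and 56.3 ± 0.879 CPM after rescue, and MYH10 the largest negative one (-2.95), at 6.96 ± 1.53 and 3.39 ± 0.0321 CPM. MYC itself had a sum of -0.09 (adjusted p = 0.856). The count of 604 was 169 without vector replicate 1, 217 without vector replicate 2, 250 without control replicate 1, 266 without control replicate 2, 373 without rescue replicate 1 and 1774 without knockdown replicate 1, where the balance turned to 730 above and 1044 below.

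**Figure D4:**
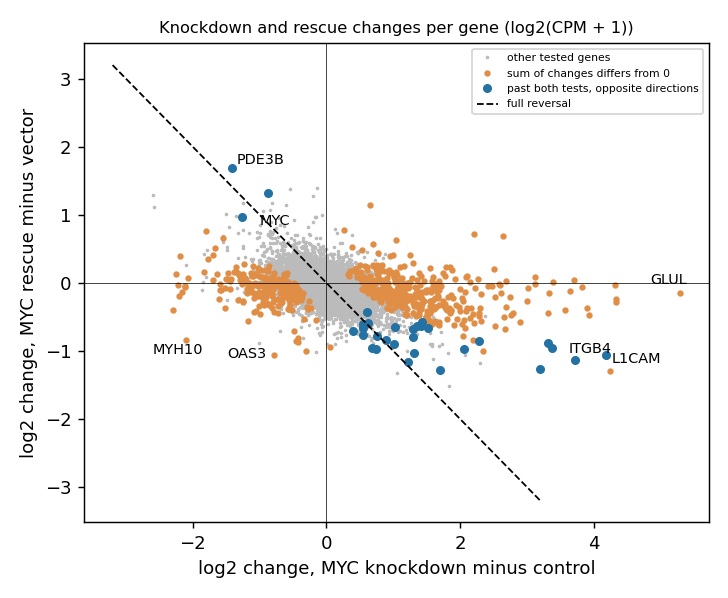
Each tested gene's log2 change after knockdown (horizontal) against its log2 change after rescue (vertical), on the log2(CPM + 1) scale, with a dashed line where the rescue would take back the whole change. Blue genes passed both tests in opposite directions (31 genes), and most orange genes, whose changes do not sum to 0, lie near a rescue change of 0, GLUL farthest to the right.

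Rescued cells were also set against the control directly. GLUL (5.77), GPR65 (4.69), CADM1 (4.56), EPB41L3 (4.27) and RCN3 (4.06) stood higher, and the growth factor EREG (-4.46), TNC (-3.41), the protease inhibitor SERPINB2 (-3.16), AKR1C1 (-3.02) and PRRG4 (-2.85) lower. EREG was at 63.2 ± 6.15 CPM in the control, 2.13 ± 0.0518 CPM in the vector and 1.92 ± 0.293 CPM in the rescue libraries, while knockdown replicates 1 and 2 held 52.8 and 4.80 CPM. AKR1C1 shares near-identical sequence with other AKR1C genes and is uncertain. Of 12625 genes 2468 passed, 1323 higher and 1145 lower, and the count was 1209 without control replicate 1, 1205 without control replicate 2 and 1538 without rescue replicate 2. Of the lists, adhesion and luminal genes passed, both higher (smallest adjusted p of any list 0.973 with an estimated correlation).

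The vector libraries, which carry the same shRNA, were compared with the knockdown to see how far the vector alone moved the cells. Of 12625 genes 7 passed, all higher with the vector: PLXDC2 (2.49), SNX10 (1.62), RFPL4A (1.44), PLEKHA7 (1.39), SAMSN1 (1.36), AHRR (1.29) and KIAA1462 (1.25), named here after their values were seen. None reached a mean of 10 CPM in the vector libraries, PLXDC2 being at 6.12 ± 1.16 CPM, and RFPL4A has a near-identical neighbour. An unadjusted p under 0.05 was reached by 589 genes. The count was 81 without knockdown replicate 1 (74 higher, 7 lower), 284 without knockdown replicate 2 (54 higher, 230 lower, so mostly the other way), 3 without control replicate 1, 3 without control replicate 2, 1 without vector replicate 1 and 0 without vector replicate 2. Of the 30 lists 12 passed camera, 8 higher and 4 lower, and none with an estimated correlation (smallest adjusted p 0.746) or with fry. Ribosome biogenesis genes (median 0.10), cytosolic ribosomal proteins (0.08), chaperones (0.11) and replication histones (0.17) were higher with the vector. Proteases (-0.19), cytokines (-0.22) and lysosome genes (-0.07) were lower. With the vector these lists thus differed from the knockdown in the direction they took after rescue, at the preset correlation alone. An effect of the vector cannot be told from the spread between the knockdown libraries, and no library was left out in these list tests. The others were the DNA replication, nucleotide, serine and cholesterol lists, higher, and brain metastasis genes, lower.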

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

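In this part, the tests of the MYC level, of the share taken back, and of the sources of the inflammatory transcripts were chosen only after the result was seen. Most large knockdown differences were still there in the rescued cells: 604 genes had knockdown and rescue changes that differed in size by a test of their sum, with GLUL (sum 5.15) and MYH10 (-2.95) at the ends. Too little MYC mRNA is argued against, since MYC in rescue minus control was 0.0373 (95% interval -0.27 to 0.35), though its protein level was not measured. A reversal of most of each change that the rescue test missed is argued against too. Over the genes changed at least 2-fold the median share taken back was 18.6% (quartiles 3.27 to 34.7%), and 69.7% of them passed the test of the sum. A weak reversal is not argued against, since 80.7% of the 456 differed the opposite way after rescue, 20 of them past the rescue test. Opposite signs were also found in 65.4% of all 12625 genes and in 61.1% of genes not called after knockdown. A lasting difference between the control line and the knockdown lines that does not follow MYC, and effects of MYC loss that the rescue left in place, cannot be told apart: among the 603 of these genes that kept the knockdown direction, 99.3% differed from the control the same way in the vector libraries, where data simulated with no change in any group gave 45.6 to 57.0%, but these libraries share the controls, carry the same shRNA and would show this in either case.

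Replicate 1 of the MYC knockdown lay nearer to the control than the other knockdown libraries did, and it held the highest level of 14 of 16 inflammatory cytokine genes among the 8 libraries. RNA or cells of the control in that library would show as about the same share in genes going either way, and the shares were 26.1% (quartiles 8.11 to 35.8%) over 28 genes low in the control and 56.0% (24.1 to 82.9%) over 5 genes low in the vector libraries, against 0.778% and 3.55% in replicate 2, so this stays open for those genes; with a 4-fold in place of a 10-fold difference to choose genes, the shares were 27.1% over 64 genes and 26.7% over 13 genes. A weaker loss of MYC stays open. The MYC difference from the control was -0.64 with replicate 1 alone and -1.06 with replicate 2 alone on the log2 scale. MYC mRNA at harvest did not by itself order the libraries on the first principal component, in a comparison of single libraries that was not the one written beforehand. Replicate 1 held 61.9 CPM and vector replicate 1 held 62.4 CPM, yet they lay at 3.79 and 16.1 on the first principal component. The rescue libraries, at 111 and 89.3 CPM, lay at 9.27 and 9.46, also farther from the control than replicate 1. An earlier MYC level and the protein were not measured. The test written beforehand does not decide, as it took genes that the rescue did not move not to follow MYC, which these data do not show. Over the 992 knockdown genes that the rescue did not move, replicate 1 lay nearer to the control than replicate 2 by a median of 22.8% of the difference between control and vector (quartiles 0.402 to 41.1%). For the inflammatory transcripts, control material as the source is argued against by the observation itself, since a mixture with the control cannot raise a gene above the control and the rest, and 15 of 16 cytokine genes stood above both control libraries in replicate 1, such as IL1B at 26.5 CPM there and 1.08 and 0.605 CPM in the controls. Handling stress that immediate early genes would mark at harvest is argued against as their source. Of 16 such genes, 2 were highest in that library, where chance gives 12.5%. Earlier handling stress was not tested. No biological explanation was tested, as the design names none.

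The share of multi-mapping reads, a row that the comparisons did not use, was above the limit that a count of 0 allows and reached 15.9% in a library.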

How the results depend on the processing

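Of 5503 alternative values for 291 gene results, 5041 kept direction and side of the threshold, 263 lost the call, 199 gained one and none reversed; of 1256 for 60 list results, 1171 kept both, 39 lost, 45 gained and 1 reversed. Where a library was left out, the lone one was assumed to vary like the other groups. Leaving out each library in turn gave 1339 to 3981 genes for knockdown, 0 to 568 for rescue, 0 to 284 for vector against knockdown, 1205 to 3420 for rescue against control, 169 to 1774 for the sum of changes and 0 to 357 reciprocal genes, 7 to 12 lists for knockdown, 9 to 15 for rescue, r of -0.467 to -0.395, MYC in knockdown of -1.06 to -0.64 and MYC in rescue of 0.60 to 0.91 (adjusted p 3.8e-04 to 0.571). The reversed result was the brain metastasis list in knockdown, with a median of -0.38 without knockdown replicate 1 and 0.26 without knockdown replicate 2 (-0.12 with all libraries, where its mean is above 0). With no filter, and so more genes tested, there were 0 genes for rescue, 0 reciprocal and 337 for the sum, 11 knockdown lists and r of -0.427. The stricter filter gave 0 genes for vector against knockdown, as none of the 7 had a mean of 5 CPM over the 8 libraries, and r of -0.487. A fit of the compared groups alone gave 2007 genes for knockdown, 452 for rescue, 1 for vector against knockdown, 225 reciprocal, and MYC in rescue at 0.755 (adjusted p 0.00193). A fold change of at least 2 left 456 genes for knockdown, 11 for rescue, 456 for rescue against control, 301 for the sum and 7 reciprocal. Other values of r were -0.402 (pseudocount 0.1), -0.501 (pseudocount 5) and -0.385 (voom). Quantile normalization gave 11 knockdown lists and MYC in rescue at 0.794 (adjusted p 0.0413), CPM per 1e6 gene reads 0.792 (0.0459) and median-of-ratios scaling 0.798 (0.0388). With an estimated correlation 0 lists passed for knockdown and 0 for rescue, and with fry 7 for knockdown and 0 for rescue. Mitochondrial ribosomal proteins (fry adjusted p = 0.0885) and proteases (0.0557) were not among the 7 fry lists for knockdown. G1 cyclins and kinases (lower, 0.0493) and neural markers (higher, 0.0023) were. Replicates share a number, with correlations of replicate differences between groups of 0.0210 to 0.168, which does not show pairing; with the number as a block, rescue had 143 genes, 120 were reciprocal, and MYC in rescue was 0.755 (adjusted p 0.00616). Where no construction is named, the cause was not tested. With 2 libraries per group and 4 residual degrees of freedom, small changes are missed, and below about 0.1 CPM a count of 0 cannot be told from low expression.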

Other observations

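In this part, the zinc finger test, the reading of the low luminal markers by level and the test of whether the luminal markers went back with MYC were chosen only after the result was seen. Gene families picked by symbol were tested as well. Host genes of small nucleolar RNAs, which guide the modification of ribosomal RNA, fell after knockdown, 7 of 15 of them (median -0.34, camera adjusted p = 6.8e-05 over 4 families; adjusted p = 0.456 with an estimated correlation), and as a family stood higher after rescue (median 0.22, adjusted p = 6.4e-07; adjusted p = 0.280 with an estimated correlation). The members named in this paragraph were chosen after their values were seen. SNHG1 was at 123 CPM in the control, 80.5 after knockdown, 97.3 with the vector and 106 after rescue, and SNHG8 fell from 81.0 to 48.1 CPM, SNHG3 from 60.6 to 36.8 CPM and SNHG12 from 28.5 to 16.3 CPM. In the vector and rescue libraries SNHG8 was at 48.6 and 54.4 CPM, SNHG12 at 19.3 and 24.5 CPM and SNHG3 at 35.2 and 35.5 CPM. Of 10 HLA genes, 4 rose after knockdown (adjusted p = 0.0102; adjusted p = 0.513 with an estimated correlation), all of them of the class II antigen presentation pathway: HLA-DPA1 (log2 change 1.84), HLA-DPB1 (1.60), HLA-DRA (1.21) and HLA-DMB (0.98). HLA-DPA1 was at 7.23 CPM in the control, 30.4 after knockdown, 23.9 with the vector and 7.71 after rescue, and the family was lower after rescue (median -0.56, adjusted p = 3.8e-05; adjusted p = 0.389 with an estimated correlation). HLA genes are similar enough to share reads, so single members are uncertain. Without knockdown replicate 1 the knockdown call of the HLA family was lost (adjusted p = 0.222), and that of the small nucleolar RNA hosts was kept (1.1e-04).

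Collagen genes rose after knockdown, 7 of 17 of them (median 0.21, camera adjusted p = 0.0102 over 4 families; adjusted p = 0.513 with an estimated correlation), and were lower after rescue (median -0.30, adjusted p = 0.00412; adjusted p = 0.433 with an estimated correlation), a family whose knockdown call was lost without knockdown replicate 1 (0.181). COL5A1 rose from 5.34 to 16.3 CPM, COL6A1 from 3.11 to 9.45 CPM and COL18A1 from 1.22 to 6.22 CPM, members again chosen after their values were seen. From vector to rescue, COL5A1 (17.6 and 18.0 CPM) and COL18A1 (5.27 and 5.42 CPM) did not fall. COL6A1 was lower (8.63 and 5.82 CPM) without being called. The members called lower after rescue were COL6A2 (-1.03) and COL8A1 (-0.43). Of 447 zinc finger genes, 65 rose and 26 fell after knockdown (adjusted p = 0.0940), so the test of a joint decrease found none; after rescue the family was placed higher (0.0144; adjusted p = 0.433 with an estimated correlation) with a median of -0.00 and no gene called.

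Luminal epithelial markers, foremost KRT19, KRT8 and AGR2, were higher after MYC knockdown in cells of a basal-like line. Luminal breast cells or their RNA in the cultures are argued against, because 0 of the 3 further markers that were under 1 CPM in the control reached 1 CPM after knockdown, while mean KRT19 went from 55.7 to 143 CPM. Of these, TFF1 had no read, CDH1, which luminal cells express abundantly, was at 0.107 and 0.119 CPM and ESR1 at 0.357 CPM in both knockdown libraries, levels below the filter that were not tested. The bound written beforehand, at most 1 such marker (AGR2 among them) at 1 CPM, was not met and was a poor choice, since GATA3 and FOXA1 were already above it in the control. GATA3 went from 3.99 and 4.24 CPM in the control to 3.36 and 3.22 CPM after knockdown, so it was lower. FOXA1 went from 3.92 and 3.27 CPM to 4.61 and 4.92 CPM (limma adjusted p = 0.0939). A change of the cells' own genes that goes back in part with MYC may stand behind the pattern, an idea found and tested on the same data: the list was lower in rescue minus vector (camera adjusted p = 0.0209; adjusted p = 0.463 with an estimated correlation; lost without vector replicate 1, 0.073, or rescue replicate 1, 0.062), with KRT19 at 138 CPM in the vector and 98.2 CPM in the rescue libraries, but 6 of 8 markers were still higher in rescue than in control (median 0.60, camera adjusted p = 0.00177; adjusted p = 0.973 with an estimated correlation).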
